A study of Mus musculus with 39 samples.

How the data were processed

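Bulk RNA sequencing was performed on duodenum of male C57BL/6 mice aged 8 weeks, in 39 libraries. Per the labels' protocols, each mouse carried a cannula into a lateral brain ventricle and drank plain water or water with ampicillin (1 g/L) and neomycin (0.5 g/L) for 48 h. It then received 3 µg of leptin or saline through the cannula, and tissue was taken 2 h after the injection. For every library the labels also give 2 h of food deprivation and a time of 3 days after placement of the cannula. Leptin is the adipocyte hormone that acts on hypothalamic circuits of energy balance. Per the labels' protocols, strand-specific total RNA libraries were made from 150 ng of RNA after depletion of ribosomal RNA and were read as paired ends.

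The values used are read counts per gene symbol as deposited by the authors, for 16358 genes and 39 libraries, with no normalisation. The deposited table is described as filtered, and 105 of its genes had a count of 0 in at least 1 library. The rule of that filter, the gene annotation and the strand setting of the counting are not given in the sources used here. The submitters' processing notes name FastQC, HISAT2, featureCounts, edgeR 3.42.0 and the mm10 genome build. Because reads were counted per symbol, members of near-identical families (the Cyp2c, Cyp3a, Ces2, Gstm, Reg3, Apol9 and H2 genes) can share reads, and the values of these genes are uncertain to that extent. Positions are from the GENCODE vM21 annotation of the same assembly, matched by symbol, which held 15999 of the 16358 symbols (97.8%). Of the genes named by rule, Zfp267 had no match.

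Library totals ranged from 30207536 to 67870777 counts (median 48282125). Residual ribosomal RNA, read from the gene Rn45s, took 2.87% to 13.3% of the counts of a library. The labels give library names of 2 kinds, here called set M and set MT. Set M held 8 Saline-water and 7 Leptin-water libraries, and set MT held 6 libraries of each of the 4 groups. The first principal component of log2 CPM held 26.6% of the variance, and set membership accounted for 92.1% of it. Set had been chosen beforehand, from the labels, as a term wherever both sets entered a fit, and comparisons with antibiotic were made within set MT. The labels number the libraries of a group as replicates and describe treatment per mouse, but do not state that each library is a separate animal. The p-values therefore measure the spread between these samples. None of the 109 pairs of libraries within a set and group held identical values. Their chi-square per degree of freedom lay between 19.8 and 202, so no library was treated as a repeat of another.

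Genes were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test on the deposited counts. TMM factors were used, genes were kept by filterByExpr on the groups of the fit, and p-values were adjusted by Benjamini-Hochberg over all genes tested. The threshold was an adjusted p of 0.05. Leptin on water was tested in the 27 water libraries with set as a term. The remaining comparisons came from 1 fit of the 24 libraries of set MT, apart from the test of whether the leptin effect differed between sets, which used the 27 water libraries. Standard errors of log2 fold changes were taken as the size of the log2 fold change over the square root of F. CPM values were computed after TMM scaling and are given as mean ± SD. All adjusted p-values for single genes in the text come from this edgeR test.

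Of 41 gene lists (processes, cell types and neighbouring tissues), 39 had at least 5 members measured. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 39 lists of a comparison. They were tested again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance in one direction. None of the lists passed in any comparison with the estimated correlation. Counts adjusted over the list alone are given beside those over all genes. Some genes, such as Per1, Slc5a1, Apoa4 and Dgat1, are in several lists, so the lists of a comparison are not independent. The 2 lists with too few members were red blood cell and mitochondrial transcripts, of which 3 and 0 members were in the table.

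Genes were named by a fixed rule. It took, for each of the 4 main comparisons, up to 6 genes with the highest and 6 with the lowest fold change among those past the threshold with a mean log2 CPM of at least 1, leaving out unnamed or predicted genes. It added up to 3 more in each direction by p, up to 4 members of each of up to 6 lists called by camera, and a fixed set of genes for every comparison (Reg3b, Reg3g, Fkbp5, Socs3, Fos, Cck and Muc2 among them). Some genes that the rule names are not reported here. For the difference tests it took up to 4 genes in each direction by p. The groups, tests, lists, naming rule and a set of alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, limma voom with quality weights, other scalings, other filters, 2 surrogate variables (sva 3.50.0), other sets of libraries, the replicate number as a block and each library left out in turn. Chosen after seeing the data were the removal of Rn45s, 3 tissue scores (exocrine pancreas, stomach and Brunner gland, smooth muscle) as covariates, and fits without 6 libraries whose pancreas score was over 4 log2 CPM or without Leptin-antibiotic replicate 3, and the MHC class II list without Saline-water replicate 12. Each fit lost only those of the 6 libraries that it held. The water fits lost Leptin-water replicates 6 and 10, and the fits of set MT lost all but Leptin-water replicate 6, which is in set M.

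The test was run on simulated counts with known changes. For leptin on water (16356 genes tested) it recovered 62% of genes changed 1.25-fold and 84% of those changed 1.5-fold. For leptin on antibiotic (16340 genes tested) it recovered 20% and 62%, for the antibiotic in saline mice 8% and 70%, and for the antibiotic in leptin mice 22% and 66%. For the difference of the leptin effect between antibiotic and water it recovered 28% at 1.5-fold, 64% at 2-fold and 96% at 3-fold. Each simulation changed 50 genes at every fold at once and drew the counts of each gene independently. With fewer changed genes the adjusted threshold is harder to pass, and spread shared between genes was not simulated. These shares may therefore be too high for the data, above all for a comparison with few or no calls.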

Results

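Duodenal transcripts were counted in 39 libraries in 4 groups, namely 14 Saline-water, 13 Leptin-water, 6 Saline-antibiotic and 6 Leptin-antibiotic libraries. The design asked how leptin given into the brain ventricle changes duodenal expression within 2 h, and whether oral ampicillin and neomycin change that response. Library totals were 30207536 to 67870777 counts. Some libraries held RNA of neighbouring tissue. The mean of the exocrine pancreas list was 4.84 to 5.62 log2 CPM in 6 libraries (Leptin-water 6 and 10, Saline-antibiotic 1, 2 and 5, and Leptin-antibiotic 3) and −1.35 to 3.16 in the others.

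**Figure D1:**
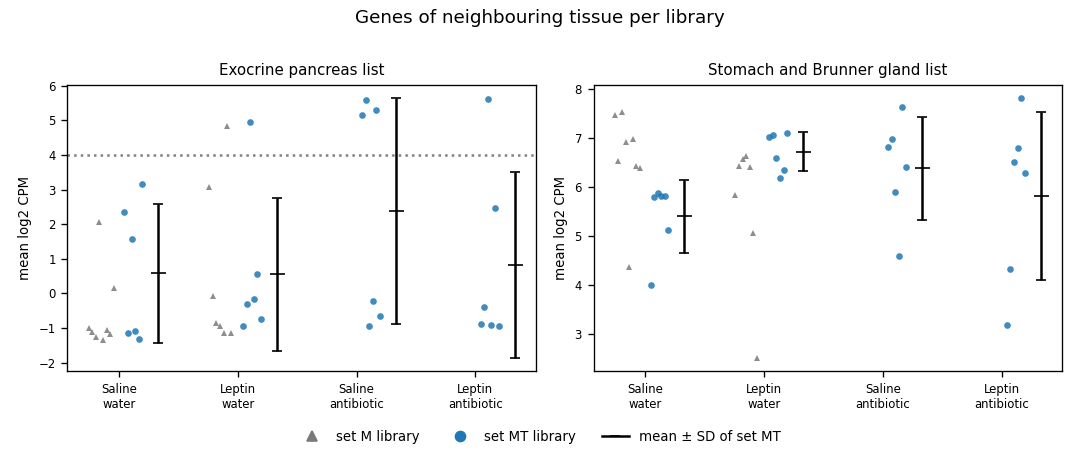
Mean log2 CPM of the exocrine pancreas list (left) and of the stomach and Brunner gland list (right) in each library, by group on the horizontal axis; triangles are set M, circles set MT, and bars the mean ± SD of the set MT libraries (n = 6). The dotted line is at 4 log2 CPM, and 6 libraries, 3 of them Saline-antibiotic, lie above it.

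Leptin in mice on water was associated with higher expression of 45 genes and lower expression of 6. Nek10, which encodes a NIMA-related kinase (GRCm38 chromosome 14, 14803415 to 15012059, plus strand), had the largest rise among the genes named by rule, from 12.2 ± 6.57 CPM (SD, n = 14) to 28.7 ± 8.66 CPM (n = 13), a log2 fold change of 1.26 (SE 0.23, adjusted p = 0.0127). Gpr17, a G protein-coupled receptor gene (chromosome 18, 31942997 to 31949636, minus strand), rose from 17.3 ± 5.89 to 30.6 ± 9.21 CPM (log2 0.85, adjusted p = 0.0103). Nr4a1, an orphan nuclear receptor of the immediate early class (chromosome 15, 101254269 to 101274795, plus strand), fell from 10.2 ± 7.18 to 4.17 ± 1.06 CPM (log2 −1.20, SE 0.23, adjusted p = 0.017), with 2 of 13 leptin libraries below every saline library. Ccn1, a matricellular protein gene of the same response class, fell with a log2 fold change of −0.74 (adjusted p = 0.0206), and G6pc, the catalytic subunit of glucose-6-phosphatase, with −0.53 (adjusted p = 0.0452).

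Other risers on water were Kirrel3, a cell adhesion gene (log2 0.92), Hsf5 (0.71), Sarm1, an NAD hydrolase gene known from axon degeneration (0.62), and Nup210l (0.47). The antisense transcript Slc13a2os also rose (0.68, adjusted p = 0.0489), but its reads may not be separable from those of its overlapping partner because the strand setting is not given. Smaller rises at higher expression were those of the chromatin remodeller Chd2 (132 ± 14.8 to 162 ± 16.7 CPM) and of Pcf11, a factor in transcript cleavage and polyadenylation (84.5 ± 6.87 to 97.7 ± 8.59 CPM). Dact2, Sertad3 and Pskh1 fell with log2 fold changes of −0.35, −0.28 and −0.16. The 51 genes had the same sign in both sets, and 49 had an unadjusted p under 0.05 in each. These are the libraries on which they were called, so this is no independent evidence.

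On water, 7 lists were called by camera, 5 up and 2 down, and none of their members passed over all genes. The unfolded protein and integrated stress response list had 17 of 22 members positive (median log2 0.11, camera adjusted p = 0.000144, adjusted p = 0.768 with an estimated correlation). Of its members, 4 were higher and 1 lower adjusted over the list alone. Its chaperone gene Hspa5 had 562 ± 89.9 CPM with leptin and 473 ± 46.5 CPM with saline (adjusted p = 0.124). The glucocorticoid response list had 13 of 19 members positive (median 0.17, camera adjusted p = 0.00339, adjusted p = 0.768 with an estimated correlation), and 6 were higher adjusted over the list alone. Per1, a clock gene that glucocorticoids also induce, had a log2 fold change of 0.53 (adjusted p = 0.0708). The circadian clock list had 14 of 20 positive (camera adjusted p = 0.0187, adjusted p = 0.768 with an estimated correlation), with 5 higher and 2 lower adjusted over the list alone.

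Xenobiotic metabolism was called up on water (26 of 31 positive, camera adjusted p = 0.00678, adjusted p = 0.821 with an estimated correlation; 0 adjusted over the list alone). Heat shock was called up too (12 of 15 positive, camera adjusted p = 0.0312, adjusted p = 0.811 with an estimated correlation; 1 adjusted over the list alone), but not with 2 surrogate variables (adjusted p = 0.0645). The fibroblast and stroma list was called down (12 of 15 negative, camera adjusted p = 0.00587, adjusted p = 0.768 with an estimated correlation; 2 lower adjusted over the list alone). Its collagen gene Col3a1 had a log2 fold change of −0.24 (adjusted p = 0.127). The enteroendocrine cell list was called down as well (20 of 25 negative, camera adjusted p = 0.012, adjusted p = 0.768 with an estimated correlation; 0 adjusted over the list alone). Its hormone granule genes Chga and Chgb had log2 fold changes of −0.44 and −0.39 in set M and −0.03 and 0.03 in set MT, and the serotonin synthesis gene Tph1 had −0.34 and −0.03. The difference between sets was not called for this list (camera adjusted p = 0.0882, adjusted p = 0.824 with an estimated correlation; 1 lower adjusted over the list alone). Of the genes reported in every comparison, Fos (log2 0.26), Socs3 (−0.28), Cck (−0.15), Muc2 (−0.04), Fkbp5 (0.21), Reg3b (−1.40) and Reg3g (−0.93) did not pass, with adjusted p between 0.293 and 0.866.

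The count of 51 was 5 in set M alone and 8 in set MT alone, and no gene was called in both sets. Of the 5 genes, 3 had the same sign in set MT, and of the 8 genes, 1 had the same sign in set M. In each set 1 of the called genes was among the 51. Across 16270 genes, which are not independent replicates, 51.7% had the same sign in both sets. Their log2 fold changes in the sets had a Pearson correlation of −0.113 and a Spearman correlation of −0.0293. Over the 9990 genes with a mean log2 CPM of at least 3 these were −0.16 and 0.0748, and 55% of the genes had the same sign. The leptin effect differed between sets by camera for 3 of the lists called up on water. The mean of the xenobiotic list was 7.13 log2 CPM with saline and 7.10 with leptin in set M, and 7.09 and 7.37 in set MT (difference: camera adjusted p = 0.00078, adjusted p = 0.824 with an estimated correlation). That of the unfolded protein list was 5.30 and 5.36 in set M and 5.27 and 5.49 in set MT (camera adjusted p = 0.000684, adjusted p = 0.402 with an estimated correlation). The glucocorticoid list had 5.83 and 5.88 in set M and 5.88 and 6.17 in set MT (camera adjusted p = 0.0374, adjusted p = 0.824 with an estimated correlation). None of their members differed adjusted over the list alone. Leaving out 1 library gave 10 (without Leptin-water 2) to 147 genes (without Saline-water 10).

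The leptin effect on water differed between sets for 7 genes. The log2 fold change was higher in set MT than in set M for Cwh43 (difference 2.99, SE 0.56), S100a6 (1.76), Krt7, a keratin of simple ductal epithelia (1.24), and Acsm3 (1.03), and the difference was negative for Mab21l2 (−0.52), each with an adjusted p of 0.0378. Cwh43 had a log2 fold change of 1.79 in set MT and −1.18 in set M. The stomach and Brunner gland list differed in the same direction (13 of 14 members positive, median 1.58, camera adjusted p = 5.71e-07, adjusted p = 0.393 with an estimated correlation; 8 members higher adjusted over the list alone). Smooth muscle (14 of 14 members negative, median −0.71, camera adjusted p = 3.98e-11) and enteric neuron and glia (17 of 19 negative, median −0.69, camera adjusted p = 2.2e-10) differed the other way, with adjusted p = 0.393 and adjusted p = 0.337 with an estimated correlation. Of their members, 13 and 10 were lower adjusted over the list alone. The count was 0 by limma voom with quality weights (1651 at an unadjusted p under 0.05), with upper quartile scaling (1736) and with tissue scores as covariates (842), and 75 by DESeq2. With 2 surrogate variables the count was 395, of which 118 were higher and 277 lower. The count was 0 to 36 when 1 library was left out.

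Leptin in mice on antibiotic was associated with higher expression of 75 genes and lower expression of 9. Fkbp5, a co-chaperone of the glucocorticoid receptor that glucocorticoids induce (chromosome 17, 28399094 to 28517527, minus strand), rose from 57 ± 21 to 158 ± 43.8 CPM (SD, n = 6 each; log2 1.48, SE 0.32, adjusted p = 0.0282), and all 6 leptin libraries exceeded every saline library. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose from 56.2 ± 3.86 to 100 ± 12 CPM (log2 0.84, adjusted p = 0.016) and Per1 from 46.6 ± 7.54 to 80.7 ± 6.74 CPM (log2 0.80, adjusted p = 0.0397). The transcriptional repressor Bcl6 (chromosome 16, 23965052 to 23988852, minus strand) rose from 20.4 ± 2.4 to 40.7 ± 4.08 CPM (log2 1.00, adjusted p = 0.0098), and Hlf, a transcription factor of clock output, rose with a log2 fold change of 1.10 (adjusted p = 0.0481). Nr4a1 fell from 12.7 ± 10.1 to 4.11 ± 1.26 CPM (log2 −1.62, SE 0.38, adjusted p = 0.0481). Without the libraries high in pancreas genes its log2 fold change was −0.65 (SE 0.34, adjusted p = 0.646).

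Muc3, a membrane-bound mucin of enterocytes, rose with leptin on antibiotic from 3390 ± 1050 to 6460 ± 1230 CPM (log2 0.94), the fucosyltransferase gene Fut4 from 74.1 ± 10.5 to 134 ± 19.9 CPM (log2 0.86), the sterol hydroxylase gene Cyp27a1 from 29.2 ± 6.23 to 54.2 ± 7.86 CPM (log2 0.90) and Tmem229b from 64.5 ± 18.7 to 132 ± 20.1 CPM (log2 1.04). Inpp5b (0.45) and Plekhh1 (0.50) had smaller rises with the same adjusted p as Fut4 and Bcl6 (0.0098). The tight junction and mucosal barrier list, which holds Muc3, was not called (12 of 21 members positive, camera adjusted p = 0.136, adjusted p = 0.617 with an estimated correlation; 1 higher adjusted over the list alone). Mblac2 (−0.76), Zfp267 (−0.40) and Sestd1 (−0.24) fell.

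The glucocorticoid response list had 17 of 19 members positive on antibiotic (median log2 0.52, camera adjusted p = 1.07e-09, adjusted p = 0.309 with an estimated correlation). Of these, 3 were higher over all genes, and 12 were higher and 1 lower adjusted over the list alone. It was the list that fry called in this comparison (adjusted p = 0.0118). Lipid absorption and chylomicrons, also called up, had 26 of 27 members positive (median 0.31, camera adjusted p = 3.35e-11, adjusted p = 0.309 with an estimated correlation), with 1 gene past the threshold over all genes and 19 adjusted over the list alone. That gene was Dgat2, an enzyme of triglyceride synthesis, at 462 ± 66.4 CPM against 266 ± 54 CPM (log2 0.80, adjusted p = 0.0183). PPAR-alpha and fatty acid oxidation had 34 of 34 members positive (median 0.25, camera adjusted p = 6.8e-11, adjusted p = 0.309 with an estimated correlation; 8 higher adjusted over the list alone), with Ppara itself at a log2 fold change of 0.59 (adjusted p = 0.0481). Angptl4, a PPAR target, had 51.4 ± 16.8 CPM against 20.3 ± 8.26 CPM and did not pass (adjusted p = 0.111).

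Amino acid and peptide uptake was called up (18 of 20 positive, camera adjusted p = 5.51e-08, 11 higher adjusted over the list alone), as was carbohydrate digestion and handling (17 of 19 positive, camera adjusted p = 1.35e-06, 10 higher adjusted over the list alone). Both had adjusted p = 0.309 with an estimated correlation, and none of their members passed over all genes. In the latter the glucose transporter gene Slc5a1 had 3610 ± 726 CPM against 2330 ± 498 CPM (adjusted p = 0.0611). Enterocyte markers were called up (16 of 17 positive, camera adjusted p = 1.35e-06, adjusted p = 0.317 with an estimated correlation; 1 higher adjusted over the list alone). The distal ileum list was called up too (6 of 6 positive, median 0.33, camera adjusted p = 0.00464, adjusted p = 0.309 with an estimated correlation; 3 higher adjusted over the list alone). Its mean was 3.14 ± 0.20 log2 CPM in Leptin-antibiotic and 2.77 ± 0.28 in Saline-antibiotic libraries, and 2.68 ± 0.21 and 2.62 ± 0.29 in Leptin-water and Saline-water libraries of set MT (n = 6 each). The difference of the leptin effect between antibiotic and water was not called for it (camera adjusted p = 0.0847, adjusted p = 0.662 with an estimated correlation; 0 adjusted over the list alone). Cell cycle genes were called down (22 of 24 negative, camera adjusted p = 1.48e-05, adjusted p = 0.541 with an estimated correlation), as were intestinal stem cell genes (14 of 15 negative, camera adjusted p = 0.00464, adjusted p = 0.463 with an estimated correlation). The exocrine pancreas list was called down with leptin (22 of 25 negative, median −1.04, camera adjusted p = 0.0259, adjusted p = 0.813 with an estimated correlation). In these 3 lists 0 members were past the threshold adjusted over the list alone. With 2 surrogate variables the call of the pancreas list ended and its direction turned to higher (adjusted p = 0.312).

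Among the other genes reported throughout, Reg3b (−1.97), Reg3g (−1.51), Socs3 (−0.10), Fos (0.23), Cck (0.25) and Muc2 (0.38) did not pass. Without the libraries high in pancreas genes no gene passed (1331 genes at an unadjusted p under 0.05 by edgeR). The log2 fold changes were then 1.80 for Fkbp5 (adjusted p = 0.256), 0.86 for Bcl6, 0.80 for Tsc22d3, 0.60 for Per1 and −0.65 for Nr4a1, and without Leptin-antibiotic 3 alone 9 genes passed. DESeq2 called 443 genes and limma voom with quality weights 96.

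**Figure D2:**
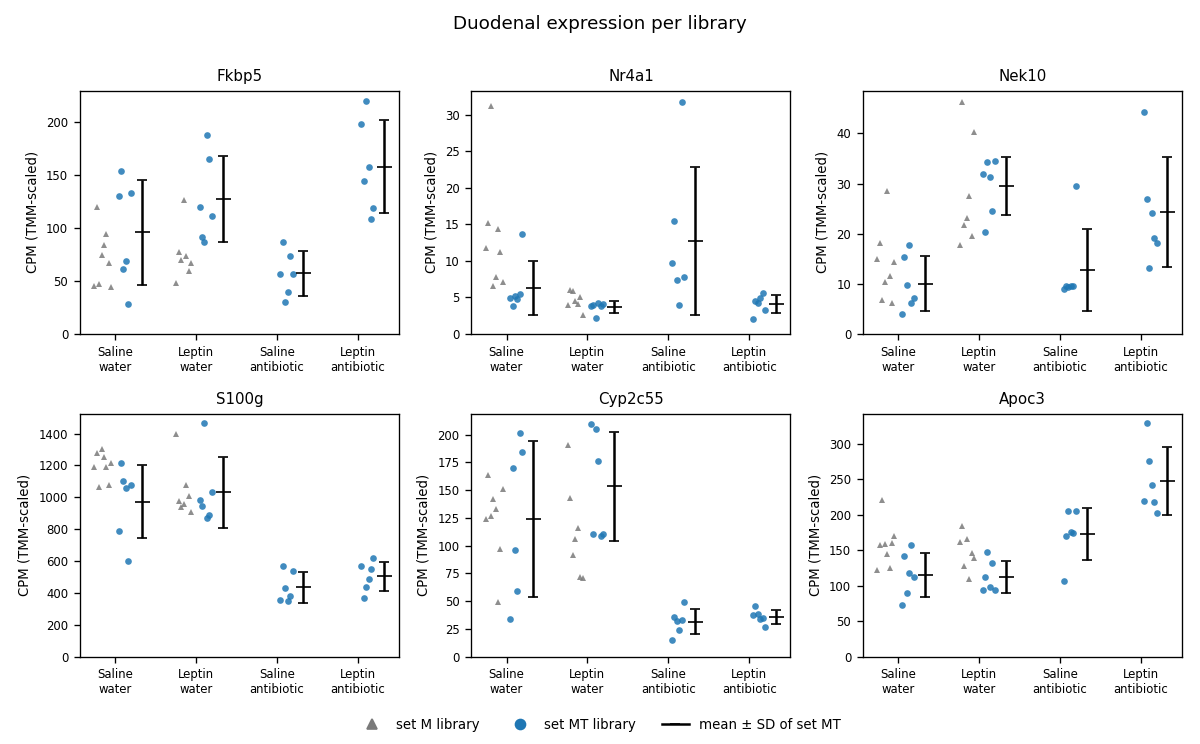
TMM-scaled CPM of 6 genes (vertical axes) in each library by group (horizontal axes); triangles are set M, circles set MT, and bars the mean ± SD of the set MT libraries (n = 6). Fkbp5 was at 158 ± 43.8 CPM in Leptin-antibiotic and 57 ± 21 CPM in Saline-antibiotic libraries, and S100g at 436 ± 96.7 CPM in Saline-antibiotic and 973 ± 230 CPM in Saline-water libraries of set MT.

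Whether the antibiotic changed the leptin response was tested directly in the 24 libraries of set MT, and no gene passed (lowest adjusted p = 0.772 by edgeR; 1043 genes at an unadjusted p under 0.05, where 817 are expected by chance). DESeq2 (1094 at an unadjusted p under 0.05) and limma voom with quality weights (1206) also called 0 genes. For Fkbp5 the log2 fold change with leptin was 1.48 on antibiotic and 0.41 on water (difference 1.06, SE 0.44, unadjusted p = 0.0226, adjusted p = 0.772), and for Bcl6 it was 1.00 and 0.48 (difference 0.52, SE 0.24, adjusted p = 0.772). Of the 84 genes called on antibiotic, 78 had the same sign in the fit of the 27 water libraries, none of them among the antibiotic libraries. Of all 16338 genes in both fits, 56% had the same sign. Called in both were 4 higher genes (Tle1, Noct, Mdm2 and Kcnk5, named after their values were seen), where independent lists give 0.207, and 1 lower gene, where they give 0.00331. The latter was Nr4a1, whose log2 fold change on antibiotic was −0.65 without the libraries high in pancreas genes. Across 16340 genes the leptin fold changes on water in set MT and on antibiotic had a Pearson correlation of 0.201 and a Spearman correlation of 0.265. By camera 15 lists differed, among them lipid absorption (24 of 27 positive, camera adjusted p = 1.41e-05) and stomach and Brunner gland (12 of 14 negative, camera adjusted p = 0.000548), both with adjusted p = 0.662 with an estimated correlation and 0 members adjusted over the list alone.

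The antibiotic in saline mice was associated with higher expression of 19 genes and lower expression of 13. S100g, the intestinal calcium-binding protein calbindin-D9k (chromosome X, 162961992 to 162964599, minus strand), fell from 973 ± 230 to 436 ± 96.7 CPM (SD, n = 6 each; log2 −1.15, SE 0.17, adjusted p = 0.00788), with all 6 Saline-antibiotic libraries below every Saline-water library of set MT. Genes that fell also included the cytochrome P450 gene Cyp2c55 (chromosome 19, 39007019 to 39042693, plus strand) from 124 ± 70.4 to 31.5 ± 11.3 CPM (log2 −1.96, adjusted p = 0.00802), the carboxylesterase gene Ces2a from 331 ± 166 to 115 ± 26.3 CPM (log2 −1.51, adjusted p = 0.00802) and Cyp3a44 (log2 −1.07, adjusted p = 0.0437). The xenobiotic metabolism list was called down (18 of 31 members negative, median −0.16, camera adjusted p = 0.0163, adjusted p = 0.727 with an estimated correlation), but not with 2 surrogate variables (adjusted p = 0.1). Its members Cyp2c55 and Ces2a passed over all genes, and 1 was higher and 9 lower adjusted over the list alone. Among risers, the membrane carbonic anhydrase gene Car4 went from 16.8 ± 6.09 to 38.7 ± 8.74 CPM (log2 1.20, adjusted p = 0.00802), Cyp4b1 from 66.5 ± 12.3 to 128 ± 24.6 CPM (log2 0.96, adjusted p = 0.00802) and the lipase-related gene Pnliprp2 from 16 ± 6.78 to 34.2 ± 5.78 CPM (log2 1.11, adjusted p = 0.0398).

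Smaller falls were those of Naip1, of the NLR family of receptors for bacterial proteins (log2 −0.53), Fcgrt, the neonatal Fc receptor (−0.49), and Best1 (−0.83). Hmox1, heme oxygenase 1, fell with a log2 fold change of −2.06 (adjusted p = 0.0388), but Saline-water 13 held 25.3 CPM against 3.14 to 4.55 CPM in the other 5 libraries. Pappa2 (1.32), Npr3, the natriuretic peptide clearance receptor (0.93), Rgn (0.93), Prr15 (0.63), Abat (0.62) and Larp1b (0.28) rose. The antimicrobial lectins Reg3b and Reg3g had log2 fold changes of −4.48 (SE 1.20, adjusted p = 0.107) and −3.43 (SE 0.92, adjusted p = 0.109) and did not pass, and their water means rested on Saline-water 9 (7100 and 3090 CPM). Fkbp5 (−0.74), Socs3 (−0.51), Fos (0.19), Cck (−0.41) and Muc2 (−0.19) did not pass either.

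The cholesterol synthesis list was called up in saline mice on antibiotic (25 of 25 members positive, median log2 0.30, camera adjusted p = 1.23e-15, adjusted p = 0.415 with an estimated correlation, fry adjusted p = 0.0295). Over all genes 1 member passed, the sterol carrier gene Stard4 (log2 0.37, adjusted p = 0.0398), and 16 were higher adjusted over the list alone. Amino acid and peptide uptake (18 of 20 positive, camera adjusted p = 0.00142) and enterocyte markers (16 of 17 positive, camera adjusted p = 0.0122) were also called up, both with adjusted p = 0.71 with an estimated correlation. None of their members passed over all genes, and 2 and 1 were higher adjusted over the list alone. Lists called down included macrophage and dendritic cell (19 of 19 negative, median −0.32, camera adjusted p = 8.34e-08) and MHC class II presentation (10 of 10 negative, median −0.62, camera adjusted p = 6.8e-06), both with adjusted p = 0.415 with an estimated correlation. None of their members passed over all genes; 1 and 8 were lower adjusted over the list alone. Saline-water 12 stood apart for MHC class II genes, with 223 CPM of H2-Eb1 (88.1 to 129 in the other 5 libraries) and 46.4 CPM of Ciita (20 to 29.2). Without it the list still had 10 of 10 members negative (median −0.43, camera adjusted p = 0.000568, adjusted p = 0.61 with an estimated correlation), but 0 instead of 8 were lower adjusted over the list alone. The T cell and intraepithelial lymphocyte list was also called down (17 of 18 negative, camera adjusted p = 0.00105, adjusted p = 0.71 with an estimated correlation; 0 adjusted over the list alone). PPAR-alpha and fatty acid oxidation was called down (camera adjusted p = 0.0101, adjusted p = 0.727 with an estimated correlation). Cell cycle was called up (camera adjusted p = 0.00169, adjusted p = 0.71 with an estimated correlation), but not with 2 surrogate variables (adjusted p = 0.0509). Both went the other way with leptin on antibiotic, a comparison that shares the Saline-antibiotic libraries. Camera called 9 lists down and 7 up. Iron and calcium uptake was called down (12 of 13 negative, camera adjusted p = 0.00105, adjusted p = 0.415 with an estimated correlation), with 1 higher and 4 lower adjusted over the list alone. S100g and Hmox1 passed over all genes, and the calcium channel gene Trpv6 was at 28.3 ± 9.13 CPM against 57.8 ± 16.3 CPM (adjusted p = 0.0606). The exocrine pancreas list was higher on antibiotic (24 of 25 positive, median 3.06, camera adjusted p = 0.000721, adjusted p = 0.71 with an estimated correlation; 0 adjusted over the list alone). Its score was over 4 log2 CPM in 3 of 6 Saline-antibiotic libraries and in 0 of the Saline-water libraries. The stomach and Brunner gland list was called up too (13 of 14 positive, camera adjusted p = 0.0188, adjusted p = 0.71 with an estimated correlation; 0 adjusted over the list alone). With 2 surrogate variables the calls of the T cell (adjusted p = 0.305), stomach and Brunner gland (0.305) and exocrine pancreas lists ended, the last with its direction turned to lower (0.0754).

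Without the libraries high in pancreas genes 17 genes passed, 8 of them among the 32. S100g, Car4 and Cyp4b1 passed there. Cyp2c55 (log2 −1.80, SE 0.43 after 0.33, adjusted p = 0.074), Ces2a (−1.35, SE 0.31 after 0.25, adjusted p = 0.074) and Pnliprp2 (1.26, SE 0.25 after 0.23, adjusted p = 0.0553) did not, and all 32 genes kept their sign (median ratio of fold changes 1.03, quartiles 0.91 to 1.14). The split of 19 higher and 13 lower became 19 and 21 with RLE factors and 16 and 28 with upper quartile scaling. It became 15 and 2 without the libraries high in pancreas genes, and 85 and 34 with tissue scores as covariates. No gene passed when the fit held the compared groups alone (1616 at an unadjusted p under 0.05).

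The antibiotic in leptin mice was associated with higher expression of 303 genes and lower expression of 69. Cyp2c55 fell from 153 ± 49.1 to 36 ± 6.21 CPM (SD, n = 6 each; log2 −2.08, SE 0.33, adjusted p = 0.00315), Ces2a from 406 ± 94.8 to 137 ± 16.6 CPM (log2 −1.55, adjusted p = 0.00315) and S100g from 1030 ± 222 to 504 ± 91.7 CPM (log2 −1.02, adjusted p = 0.00336), in each case with all 6 Leptin-antibiotic libraries below every Leptin-water library of set MT. The glutathione transferase gene Gstm1 (−1.20, adjusted p = 0.0239) and the P450 gene Cyp3a11 (−0.89, adjusted p = 0.0483) fell too, as did Car8 (−0.52), Adgrf1 (−0.77) and Ikbkg (−0.34). Cyp4b1 rose from 83 ± 18.5 to 182 ± 36.6 CPM (log2 1.14, adjusted p = 0.00207) and Apoc3, an apolipoprotein of triglyceride-rich particles (chromosome 9, 46232933 to 46235636, minus strand), from 113 ± 22.4 to 248 ± 47.9 CPM (log2 1.15, adjusted p = 0.00268). Further risers were Enpp7, the intestinal alkaline sphingomyelinase (1.84), Gpr151 (1.51), Pappa2 (1.49), Ccdc170 (1.38), Arsa (0.53) and Ndufb10 (0.43), and the near-identical pair Apol9a (1.63) and Apol9b (1.95), for which Leptin-antibiotic 2 stood above the rest at 103 and 64.2 CPM.

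In leptin mice on antibiotic the amino acid and peptide uptake list was called up, with 20 of 20 members positive (median log2 0.38, camera adjusted p = 2.69e-10, adjusted p = 0.588 with an estimated correlation), with 7 past the threshold over all genes and 12 adjusted over the list alone. These included the amino acid transporters Slc7a8 (0.80), Slc16a10 (0.57) and Slc7a7 (0.37) and the peptidase Naaladl1 (0.82). Lipid absorption and chylomicrons had 25 of 27 positive (median 0.25, camera adjusted p = 8.23e-07, adjusted p = 0.588 with an estimated correlation; 4 past the threshold over all genes, and 12 higher and 2 lower adjusted over the list alone), with Apoa4 (0.70), Dgat1 (0.33) and Pla2g12b (0.36) beside Apoc3. Enterocyte markers (17 of 17 positive, camera adjusted p = 1.92e-06), carbohydrate digestion (16 of 19 positive, camera adjusted p = 0.000144) and cholesterol synthesis (22 of 25 positive, camera adjusted p = 0.000496) were called up, each with adjusted p = 0.588 with an estimated correlation. Past the threshold over all genes were 2, 1 and 2 of their members, and adjusted over the list alone 6, 10 and 4 were higher and 0, 1 and 0 lower. The 2 of the enterocyte list were Apoa4 and Dgat1, which the lipid absorption list also holds. Trehalase, Treh (0.63), and Msmo1 (0.41) were among those of the other lists. The distal ileum list was called up beside them (4 of 6 positive, camera adjusted p = 0.037, adjusted p = 0.588 with an estimated correlation; 3 higher adjusted over the list alone). Its members Enpp7 (1.84) and, named after its value was seen, the bile acid transporter gene Slc10a2 (0.83, adjusted p = 0.0462) passed over all genes. The comparison of leptin on antibiotic uses the same Leptin-antibiotic libraries. Their lipid absorption mean was 8.16 log2 CPM. It was 7.89 in Leptin-water, 7.84 in Saline-antibiotic and 7.80 in Saline-water libraries of set MT. In saline mice the antibiotic gave no call for lipid absorption, carbohydrate digestion or distal ileum (camera adjusted p = 0.642, 0.556 and 0.564). The amino acid, enterocyte and cholesterol lists were called up there.

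Smooth muscle genes were called up as well (13 of 14 positive, camera adjusted p = 0.000144, adjusted p = 0.588 with an estimated correlation; 2 higher adjusted over the list alone). Actg2, enteric smooth muscle actin, passed at 121 ± 13.9 CPM against 74.1 ± 17.4 CPM (adjusted p = 0.0131). B and plasma cell genes (11 of 11 negative, camera adjusted p = 0.00101) and intestinal stem cell genes (13 of 15 negative, camera adjusted p = 0.00651) were called down, both with adjusted p = 0.588 with an estimated correlation and with 1 member lower adjusted over the list alone. Reg3b (−3.20, adjusted p = 0.126), Reg3g (−2.26, adjusted p = 0.165), Fkbp5 (0.32), Socs3 (−0.19), Fos (0.04), Cck (−0.07) and Muc2 (0.20) did not pass. Reg3b was at 14.6 ± 8.37 CPM against 135 ± 68.1 CPM, and Reg3g at 19.1 ± 6.1 CPM against 92.3 ± 48.5 CPM. For both, all 6 Leptin-antibiotic libraries lay below every Leptin-water library of set MT. The fit shared its spread with Saline-water 9, which stood apart for both genes and is not in this contrast. The split of 303 higher and 69 lower became 135 and 89 with upper quartile scaling, and the count ranged from 73 (without Leptin-water 9) to 650 (without Saline-water 13).

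The antibiotic comparisons in saline and in leptin mice share no library. They had 14 higher genes in common, where independent lists give 0.352, and 7 lower genes, where independent lists give 0.0549. Named by rule among them were Cyp2c55, Ces2a, S100g and Cyp3a44 among the lower and Cyp4b1, Car4, Pappa2, Npr3, Prr15, Abat, Rgn and Larp1b among the higher. Across 16340 genes the fold changes had a Pearson correlation of 0.389 and a Spearman correlation of 0.347. Of the 32 genes called in saline mice, 31 had the same sign in leptin mice, and of all genes 61.3% did.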

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

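All tests of explanations in this part were chosen after the results they address had been seen. The difference of the leptin effect between sets was a comparison set beforehand.

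A gap test for single libraries far from their group was run 275 times, each on 1 gene or library measure in 1 group of 6 set MT libraries. Of these tests 22 had such a library, where 13.8 are expected by chance for independent, normally distributed values. Related genes share libraries and CPM values are skewed, so that expected number is only a rough guide. Among Saline-water libraries of set MT, replicate 9 held 7100 CPM of Reg3b (others 24.8 to 268) and 3090 CPM of Reg3g (others 37 to 179). Replicate 10 held 4.32 CPM of Best1 (2.45 to 2.88) and 955 CPM of Ftl1 (634 to 754). Replicate 12 held 46.4 CPM of Ciita (20 to 29.2) and 223 CPM of H2-Eb1 (88.1 to 129). Replicate 13 held 25.3 CPM of Hmox1 (3.14 to 4.55) and 15.5 CPM of Cd4 (8.59 to 11.2). Replicate 14 held 18.5 CPM of the pancreatic gene Cela1 (4.14 to 8.79) and 2.07 CPM of Sycn (0.172 to 0.781).

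Among Saline-antibiotic libraries, replicate 1 was low for Cyp4b1 at 80.2 CPM (128 to 148) and for Cyp3a44 at 5.81 CPM (11.3 to 13.2). Replicate 3 was high for Reg3g at 175 CPM (9.5 to 71.3) and for Msmo1 at 77.9 CPM (59.3 to 60.4). Among Leptin-water libraries of set MT, replicate 10 held 1470 CPM of S100g (871 to 1030) and had a pancreas score of 4.94 log2 CPM (−0.943 to 0.546). Replicate 12 held 84.9 CPM of Slc37a4 (49 to 61.2). Among Leptin-antibiotic libraries, replicate 2 held 64.2 CPM of Apol9b (7.87 to 26.9) and 103 CPM of Apol9a (13.4 to 41.2). Replicate 3 held 173 CPM of Fut4 (118 to 134). Its total was 67870777 counts, or 67.9 in the unit in which the others had 45.8 to 52.3. Malat1 took 0.411% of its counts (0.935% to 1.15% in the others).

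By camera the leptin effect differed between antibiotic and water in 15 lists and between sets in 13 lists, and in 0 of either with an estimated correlation. For single genes the difference between antibiotic and water had 0 calls by edgeR (1043 at an unadjusted p under 0.05) and 0 by DESeq2 and limma voom. Of the 99 other splits of the libraries 98 also called 0, and the highest called 42. A count of 0 is reached by 100 of 100 splits whatever the data hold, so the splits decide nothing here.

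The leptin effect on water differed between sets for Acsm3 (1.03), Dhrs9 (1.62), S100a6 (1.76), Mab21l2 (−0.52), Krt7 (1.24), Cwh43 (2.99) and Gldc (2.29), as log2 of set MT minus set M. Dhrs9 and Gldc lie outside the naming rule and are given because the count is small. The real split was the 1 of 100 that gave 7 or more genes (highest other 2). The other splits moved the set labels themselves, which left the large difference between sets in the spread. They could therefore hardly call genes, and this count does not speak on chance. A different amount of pyloric or stomach tissue per library could account for part of this. With the stomach and Brunner gland score as a covariate all 7 kept their sign and none passed. The ratio of the differences had a median of 0.66 (quartiles 0.57 to 0.71), and the median size was 0.906 after 1.62. A mean over a gene list measures tissue only in part, so the remaining difference does not decide whether this tissue was the whole cause. The smooth muscle list also differed between sets (14 of 14 members negative, camera adjusted p = 3.98e-11, adjusted p = 0.393 with an estimated correlation; 13 lower adjusted over the list alone). With the exocrine pancreas, stomach and Brunner gland, and smooth muscle scores as 3 covariates the median ratio was 0.629 (0.482 to 0.706) and the median size 0.864. That fit called 0 genes by edgeR, and 842 had an unadjusted p under 0.05, against 1612 without the scores and 818 expected by chance. Tissue makeup and a different leptin response in the sets therefore cannot be told apart for these genes, since the stomach and smooth muscle lists moved with leptin in different directions in the sets.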

How the results depend on the processing

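Fits with Rn45s removed, tissue scores, or without the libraries high in pancreas genes or Leptin-antibiotic 3, and the MHC class II list without Saline-water 12, were chosen after the data were seen. No named gene that was past the threshold in the main fit or in the other setting changed sign. Some genes past it in neither did. Reg3g had a log2 fold change of −0.93 with leptin on water and 0.37 in set M alone. Chgb had −0.20 with leptin on water and 0.03 in set MT alone. Of the values of named genes past the threshold, 166 of 225 stayed past it for leptin on water, 154 of 236 for leptin on antibiotic, 186 of 227 and 357 of 390 for the antibiotic in saline and leptin mice, and 30 of 50 for the difference between sets. In the order leptin on water, leptin on antibiotic, antibiotic in saline mice and antibiotic in leptin mice, the counts of 51, 84, 32 and 372 became 173, 443, 183 and 780 by DESeq2, 153, 14, 119 and 997 with tissue scores, and 33, 0 (edgeR; 1331 at an unadjusted p under 0.05), 17 and 205 without the libraries high in pancreas genes. By limma voom with quality weights they were 228 on water and 81 and 1394 for the antibiotic. With upper quartile scaling 51 were called for leptin on antibiotic and 224 for the antibiotic in leptin mice. With 2 surrogate variables the antibiotic gave 57 and 631. With all 39 libraries in 1 fit the last 3 were 548, 216 and 1917. Without Leptin-antibiotic 3 leptin on antibiotic gave 9 and the antibiotic in leptin mice 137. The antibiotic in saline mice gave 0 with the 2 compared groups alone (edgeR; 1616 at an unadjusted p under 0.05). Leptin on water gave 20 with no set term, 5 in set M and 8 in set MT. The 7 genes differing between sets (6 higher and 1 lower) became 75 by DESeq2 and 395 with 2 surrogate variables (118 higher and 277 lower). They became 0 by voom, 0 with upper quartile scaling, 0 with tissue scores and 3 without the libraries high in pancreas genes, 0 of them shared. The difference between antibiotic and water was 0 in all settings. The split of 19 higher and 13 lower was 19 and 21 with RLE factors and 19 and 22 without Rn45s. It was 15 and 2 without the libraries high in pancreas genes and 85 and 34 with tissue scores. Apart from fewer libraries, the cause was not tested.

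Replicate numbers showed no pairing of the libraries: same-numbered deviations correlated at −0.212 to 0.503 over 6 antibiotic pairs (1 over 0.1) and −0.197 to 0.206 over 13 water pairs (3 over 0.1), and 1 pair of each had its own number as best partner. On water the numbers of set MT run from 9 to 14 for saline and from 8 to 13 for leptin, and number 8 joins libraries of different sets. Neither these correlations nor the replicate block can therefore exclude a pairing of mice on water. With the replicate block, 0 genes were called for leptin on water (edgeR; 1700 at an unadjusted p under 0.05), 1 for leptin on antibiotic and 0 for the difference between antibiotic and water.

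Lists called with an estimated correlation numbered 0 in all 6 comparisons. With fry they were 0 on water, 1 for leptin on antibiotic, 1 for the antibiotic in saline mice and 0 in the other 3. With 2 surrogate variables 9 lists were called in saline mice. Of the lists called by camera, 6 of 7 for leptin on water, 18 of 20 for leptin on antibiotic, 9 of 16 and 13 of 14 for the antibiotic in saline and leptin mice, 10 of 15 for the difference between antibiotic and water and 12 of 13 for that between sets were then called in the same direction. The Pearson correlation of leptin on water with leptin on antibiotic was 0.159, and 0.285 over genes with a mean log2 CPM of at least 3.

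Leaving out 1 library gave 10 to 147 genes for leptin on water, 9 to 183 for leptin on antibiotic, 14 to 100 and 73 to 650 for the antibiotic in saline and leptin mice, 0 for the difference between antibiotic and water and 0 to 36 between sets. For leptin on water the counts over 1.5 times away were, without Leptin-water 2, 7, 11, 10, 3 and 12, 10, 20, 19, 27, 29 and 30, and without Saline-water 7, 9, 3, 4, 2, 11, 1, 12, 5 and 10, 17, 20, 22, 27, 29, 30, 31, 31, 125 and 147. For leptin on antibiotic they were 9, 10 and 28 without Leptin-antibiotic 3, 2 and 1, 10, 13, 18, 46 and 182 without Saline-antibiotic 1, 4, 5, 2 and 6, 46, 156 and 183 without Saline-water 12, 10 and 13, and 47 and 53 without Leptin-water 9 and 10. For the antibiotic in saline mice they were 14, 15, 20 and 20 without Saline-antibiotic 2, 4, 5 and 6, 16, 18 and 100 without Saline-water 10, 12 and 9, and 19 without Leptin-antibiotic 4. For the antibiotic in leptin mice they were 73, 85 and 125 without Leptin-water 9, 8 and 11, 91 and 137 without Leptin-antibiotic 2 and 3, 228 without Saline-antibiotic 4, and 216 and 650 without Saline-water 12 and 13. Between sets they were 0 without any of Leptin-water 1, 3, 5, 7, 8, 9, 10 and 13 or Saline-water 1, 2, 3, 4, 6, 9, 10, 12 and 14, 1 and 31 without Saline-water 11 and 5, and 11 and 36 without Leptin-water 11 and 6.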

Other observations

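The tests of explanations in this part were chosen after the results were seen, apart from the villus and crypt test, whose bound was written before its result.

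Further lists were called by camera with leptin on antibiotic. Goblet cell genes had 11 of 15 members positive (median log2 0.25, camera adjusted p = 0.00464, adjusted p = 0.309 with an estimated correlation; 4 higher adjusted over the list alone). Bile acid and FXR genes had 7 of 7 positive (camera adjusted p = 0.0259, adjusted p = 0.309 with an estimated correlation; 2 higher adjusted over the list alone), a call that ended with 2 surrogate variables (adjusted p = 0.0673). Fatty acid synthesis had 11 of 16 negative (camera adjusted p = 0.0259, adjusted p = 0.334 with an estimated correlation; 3 lower adjusted over the list alone).

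With the antibiotic in leptin mice, interferon response genes had 28 of 40 members positive (median 0.19, camera adjusted p = 0.0363, adjusted p = 0.82 with an estimated correlation). Of these 2 passed over all genes, and 10 were higher and 3 lower adjusted over the list alone. The call ended with 2 surrogate variables (adjusted p = 0.0703).

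The 84 genes called with leptin on antibiotic, Fkbp5, Tsc22d3 and Per1 among them, came from the 1 of 100 splits that called as many (highest other 1). Without the libraries high in pancreas genes all 84 kept their sign, with a median ratio of fold changes of 0.808 (quartiles 0.725 to 0.906). The median size was 0.391 after 0.486. These folds therefore did not rest on those libraries alone. The genes were called partly on the remaining libraries, so the kept signs are no independent evidence. For a higher villus share over crypt, that score as a covariate left a ratio of 0.742 (0.676 to 0.815) and a median size of 0.346. Both adjustments ended every call, the former with 4 fewer antibiotic libraries and both with smaller folds. Leptin may act in the same direction on water, where 92.9% of the 84 genes had the same sign (56% of all genes) but a median size of 0.136. Stress or handling time, which the labels do not give per mouse, stays open.

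The 32 genes called with the antibiotic in saline mice came from the 1 of 100 splits that called as many (highest other 2). Without the libraries high in pancreas genes their fold changes had a median ratio of 1.03 (quartiles 0.91 to 1.14), so they did not rest on those libraries. The genes were called partly on the remaining libraries, so this ratio is no independent evidence. In leptin mice, other libraries, 96.9% had the same sign (61.3% of all genes), with a median size of 0.64 against 0.845. An effect of the antibiotic shared by both groups is a hypothesis consistent with these values, and whether it runs through the microbiota was not tested.

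For leptin on water, 1 of 100 splits gave as many as 51 genes (highest other 22). For the antibiotic in leptin mice, 1 of 100 gave as many as 372 (highest other 53).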
